A study of Phanerodontia chrysosporium with 15 samples.

How the data were processed

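The series holds poly(A) RNA sequencing of the white-rot fungus Phanerochaete chrysosporium, strain RP78, registered under the genus name Phanerodontia. Mycelium was grown on plates of 1% malt and 3% agar at 37 °C and harvested after 3 days. It grew without preservative (control) or with 1 of 2 copper-based wood preservatives. Tanalith E3474 combines copper with the azole fungicides tebuconazole and propiconazole. Korasit KS2 combines copper with quaternary ammonium compounds (QAC). Each product was first diluted 145-fold and passed through a 0.22 µm filter, and was then used at a final dilution of 37000-fold (written 37,000X, the weaker treatment) or 18000-fold (18,000X, the stronger one). According to the labels, Tanalith at 37,000X gave 3 mg/L copper, 59 ng/mL of each azole, 0.19 µM tebuconazole and 0.17 µM propiconazole. Korasit at 37,000X gave 2.75 mg/L copper and 4.9 mg/L QAC. The 5 groups have 3 libraries each, which the labels call biological replicates. All 15 libraries carry the same batch label, so no comparison within batches was needed. The labels do not say whether the replicates came from cultures started on different days.

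There is 1 deposited table per library, with the same 12256 numeric protein IDs in each and 2 blank rows at the end. The blank rows hold no value, so they take a share of 0 of the counts. The authors deposited raw read counts per protein ID, per the file headers, and these counts were the values tested here. They also deposited RPKM, and dividing the counts by these RPKM values gave a whole-number transcript length (within 0.01 nt) for all 11774 IDs with a read. The deposited TPM column was not used in any comparison, and it sums to the same total in each library. A further deposited column headed CPM was treated here as a score, since it sums to between 824002 and 1318861 per library, with a different sum in each. The per-library constant behind that column, divided by the library's total count, differed from the library's TMM factor by a median of 1.03% and at most 2.63%. DESeq2 1.32 is named in the submitters' processing notes, with no role given. The aligner, the counting program, the genome build and the treatment of strand and of reads shared between paralogs are not given in the sources used here. Counts of near-identical or overlapping genes are therefore uncertain.

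The tables do not pair the protein IDs with gene names or product descriptions, and no reference for this organism was used. The gene lists fixed before the data were examined (among them cytochrome P450 enzymes, ergosterol synthesis and copper handling) could therefore not be matched to IDs and were not tested. IDs are given as the tables print them, with no name, function or position. The rule for the IDs named in the text was also fixed before the data were examined. For tables without names it takes, per comparison, the 2 IDs with the largest rise and the 2 with the largest fall among those past the threshold. Each must have a mean CPM of at least 5 in the higher group, and all libraries of the first group must lie on the same side of all libraries of the second. This last condition was not applied to the interaction, which has 4 groups, and for it the mean CPM of at least 5 is that of the highest group.

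Total counts ranged from 25348219 to 73943693 per library, with a median of 43152836. A count of 0 in a library allows up to 3 counts, which by raw total count, without the TMM factor, is 0.0406 CPM in the deepest library and 0.118 CPM in the shallowest. Such limits and all counting intervals cover counting error only. Of the 12256 IDs, 482 had no read in any library. Replicates were compared before use. The 105 pairs of libraries contained 0 pairs with identical counts. The 15 pairs of replicates differed by 65.0 to 463 times the sampling noise (chi-square per degree of freedom), which 2 deposits of the same library would not. This does not show that the cultures were independent, and each library was counted as a replicate because the labels call it one.

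Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Libraries were scaled with TMM factors, IDs with low counts were removed with filterByExpr, and 11511 IDs were tested. The 263 other IDs with reads were not tested. A quasi-likelihood model with 1 mean per group was fitted to all 15 libraries together (glmQLFit and glmQLFTest), which left 10 residual degrees of freedom. An ID was said to have changed, risen or fallen when its Benjamini-Hochberg adjusted p over the IDs tested was below 0.05. The comparisons were each treatment against the control, the 18,000X against the 37,000X dilution of each product, Tanalith against Korasit at each dilution, and the interaction of product and dilution. The interaction is the log2 change from 37,000X to 18,000X under Tanalith minus the same change under Korasit. CPM values in the text use the TMM-scaled library size. Log2 fold changes are given with a standard error (SE), and means of 3 libraries with a standard deviation (SD). Log2 CPM for the principal components used a prior count of 2.

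The edgeR procedure was tested on simulated counts with known changes. They were drawn from each ID's mean over all 15 libraries, its estimated spread and the real library sizes. For Tanalith 37,000X against the control, 81.8% of 66 IDs changed 4-fold, 31.3% of 67 IDs changed 2-fold and 1.49% of 67 IDs changed 1.5-fold were recovered, with 4 false calls among 11475 IDs. For the 2 Tanalith dilutions the recovery was 80.3% at 4-fold, 40.3% at 2-fold and 0% at 1.5-fold, with 7 false calls among 11470 IDs. For the 2 Korasit dilutions it was 81.8% at 4-fold, 37.3% at 2-fold and 2.99% at 1.5-fold, with 4 false calls among 11482 IDs. All recovered IDs in these 3 simulations had the simulated direction. Comparisons that share the control libraries were set beside 20 simulations of unchanged groups. In each, all 15 libraries were drawn anew, the controls included, from each ID's control mean and 1 spread per ID for all groups. All simulated treatments were compared with the same simulated controls.

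The alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios (RLE) scaling, no filter on low counts, the replicate number as a block, a fit of only the groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. Scaling by total count, scaling by the constants of the deposited CPM column, removal of each library's trend over transcript length (loess, span 0.3) and thinning of all libraries to equal depth were chosen after seeing the data. So were the IDs that changed in the same direction in all 4 treatments, the IDs that differed between products at both dilutions, and the correlation of the Korasit dilution effect with the Tanalith effect. Exact tests and figures were made with SciPy and matplotlib.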

Results

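RNA from the mycelium of Phanerochaete chrysosporium, a white-rot fungus that degrades lignin, was sequenced in 15 libraries, 3 in each of 5 groups. The groups were a control without preservative and mycelium grown for 3 days with Tanalith (copper with the azoles tebuconazole and propiconazole) or Korasit (copper with quaternary ammonium compounds), each at the weaker dilution of 37,000X or the stronger dilution of 18,000X. Azoles are known to inhibit a demethylase of sterol synthesis, and quaternary ammonium compounds are known to disrupt membranes. The series title gives resistance mechanisms and the detoxification of azoles as the purpose. Total counts per library were 28261581 to 52687141 in the control, 25348219 to 66936728 in Tanalith 37,000X, 32468238 to 45272775 in Tanalith 18,000X, 45354360 to 73943693 in Korasit 37,000X and 30373782 to 43152836 in Korasit 18,000X. Between 11333 and 11608 of the 12256 protein IDs had at least 1 read in a library. The tables do not pair these IDs with gene names, so IDs stand for genes throughout.

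The preservatives separated the libraries from the control more than the products or dilutions separated them from each other. The first principal component, with 39.99% of the variance, placed the control at a mean of -94.7 ± 1.26 (SD, n = 3). Tanalith 37,000X lay at 28.8 ± 5.23, Tanalith 18,000X at 23.5 ± 0.512, Korasit 37,000X at 31.7 ± 9.91 and Korasit 18,000X at 10.6 ± 8.31 (SD, n = 3 each). On the second component, with 13.0% of the variance, the Korasit 18,000X libraries lay between -57.5 and -44.3, below the 12 other libraries, which lay between -12.7 and 32.6. Pairs of replicates correlated across IDs with Pearson's r between 0.957 and 0.992 in log2 CPM, where IDs are not independent replicates. Some libraries stood apart from their group. The SD of the log2 deviation from the group mean was 0.625 in control replicate 3, 0.578 in Tanalith 37,000X replicate 3 and 0.524 in Korasit 18,000X replicate 3. The next value was close, at 0.501 in Tanalith 37,000X replicate 2, and the lowest was 0.289. The 3 libraries at 0.524 or above also scored highest on the third component (12.3% of the variance), at 32.4, 59.1 and 47.4. They had the fewest IDs with reads, at 11333, 11403 and 11340, against 11456 or more in the other libraries. Replicate 3 of Korasit 37,000X and of Tanalith 18,000X scored 0.147 and -20.7. Deviations of the 3 libraries correlated in pairs at 0.146, 0.149 and 0.284. A deviation common to replicate 3 in part of the groups therefore stays open.

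**Figure D1:**
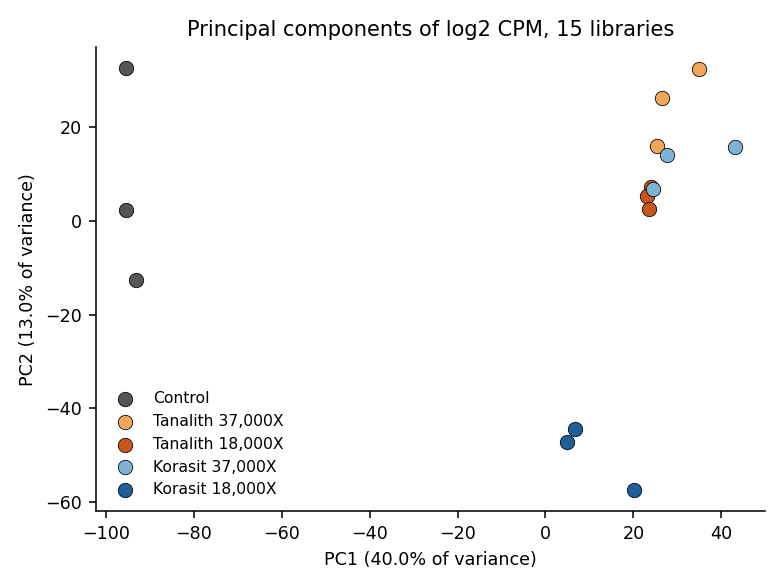
Principal components of log2 CPM for the 15 libraries, 1 point per library, with the share of variance on each axis. The control libraries lie at -95.4 to -93.2 on the first component and all treated libraries at 4.79 or above, while the 3 Korasit 18,000X libraries lie lowest on the second component.

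Tanalith changed 42.8% of the tested IDs at 37,000X and 39.9% at 18,000X against the control. At 37,000X, 2492 IDs rose and 2434 fell against the control, of which 1136 rose and 1622 fell by 2-fold or more. ID 6328981 rose from 175 ± 49.5 CPM in the control to 21344 ± 4251 CPM (SD, n = 3 each), with a log2 fold change of 6.93 ± 0.43 (SE, adjusted p = 3.56e-08). ID 6428572 rose from 0.119 ± 0.116 CPM, a total of 21 counts in the 3 control libraries, to 33.2 ± 19.9 CPM, a log2 fold change of 7.91 ± 0.93 (SE, adjusted p = 1.18e-05). ID 6333962 fell from 267 ± 49.2 to 0.656 ± 0.985 CPM, a log2 fold change of -8.89 ± 0.94 (SE, adjusted p = 4.64e-06), which was -11.15 without Tanalith 37,000X replicate 2. ID 6471926 also fell, by -8.59 ± 1.53 (log2, SE, adjusted p = 0.000451), but its 3 control libraries ranged from 8.12 to 666 CPM.

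At 18,000X, Tanalith raised 2345 IDs and lowered 2245, of which 1140 rose and 1458 fell by 2-fold or more. ID 6328981 stood at 20627 ± 5341 CPM, with a log2 fold change of 6.88 ± 0.43 (SE, adjusted p = 3.68e-08). ID 6104869 had 1132 counts in the 3 Tanalith 18,000X libraries and 1 count in the 3 control libraries. That is a ratio of 1395 with a 95% exact binomial counting interval of 249.9 to 55152, which leaves out the spread between replicates. By edgeR the log2 fold change was 10.05 ± 2.33 (SE, 95% interval 5.06 to 15.03, adjusted p = 0.00318). The level of this ID was 0.88 CPM in Tanalith 18,000X replicate 2 against 15.4 and 13.5 CPM in the other replicates. ID 6472142, among the more abundant transcripts of the control at 1377 ± 539.8 CPM, fell to 6.64 ± 2.82 CPM (log2 fold change -7.69 ± 1.18 SE, adjusted p = 0.000127). ID 6410002 fell from 16.1 ± 12.7 to 0.0917 ± 0.111 CPM, the latter from 12 counts (log2 fold change -7.35 ± 1.80 SE, adjusted p = 0.00454). Its control libraries were uneven, at 24.7, 22.2 and 1.502 CPM, and the log2 fold change was -9.08 without Tanalith 18,000X replicate 2.

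These values came from edgeR's quasi-likelihood test with 11511 IDs tested, and DESeq2 gave 5337 changed IDs at 37,000X and 4929 at 18,000X. A fit of the Tanalith 37,000X and control libraries alone gave 3237 changed IDs. Scaling by total count in place of TMM moved the median log2 fold change at 37,000X by -0.27 and turned the split from 2492 higher and 2434 lower into 1504 higher and 3320 lower.

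Korasit, which contains copper but no azole, changed about as many IDs. At 37,000X, 2466 IDs rose and 2484 fell against the control, of which 1082 rose and 1668 fell by 2-fold or more. ID 6428572, the same ID that led the Tanalith 37,000X rises, rose to 53.2 ± 25.5 CPM (log2 fold change 8.58 ± 0.94 SE, adjusted p = 6.27e-06), and ID 6409424 rose from 0.564 ± 0.320 to 42.4 ± 11.6 CPM (6.25 ± 0.54 SE, adjusted p = 6.85e-07). ID 6417800 fell from 791 ± 255 to 0.283 ± 0.0319 CPM, a log2 fold change of -11.42 ± 0.87 (SE, adjusted p = 2.33e-07). ID 6472142 fell to 0.549 ± 0.407 CPM, a log2 fold change of -11.37 ± 1.39 (SE, adjusted p = 1.62e-05).

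At 18,000X, Korasit raised 2105 IDs and lowered 2127, of which 1147 rose and 1235 fell by 2-fold or more. ID 6222934 rose from 3.34 ± 1.70 to 444 ± 95.1 CPM (log2 fold change 7.08 ± 0.41 SE, adjusted p = 2.19e-08) and ID 6343483 from 28.1 ± 14.2 to 2987 ± 870.04 CPM (6.73 ± 0.62 SE, adjusted p = 1.32e-06). ID 6472142 fell to 4.13 ± 1.92 CPM (log2 fold change -8.38 ± 1.22 SE, adjusted p = 9.5e-05) and ID 6417800 to 3.81 ± 0.691 CPM (-7.69 ± 0.73 SE, adjusted p = 1.94e-06). DESeq2 gave 5295 changed IDs at 37,000X and 4614 at 18,000X. With scaling by total count the split was 1753 higher and 2786 lower at 37,000X, and 1386 higher and 2937 lower at 18,000X.

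**Figure D2:**
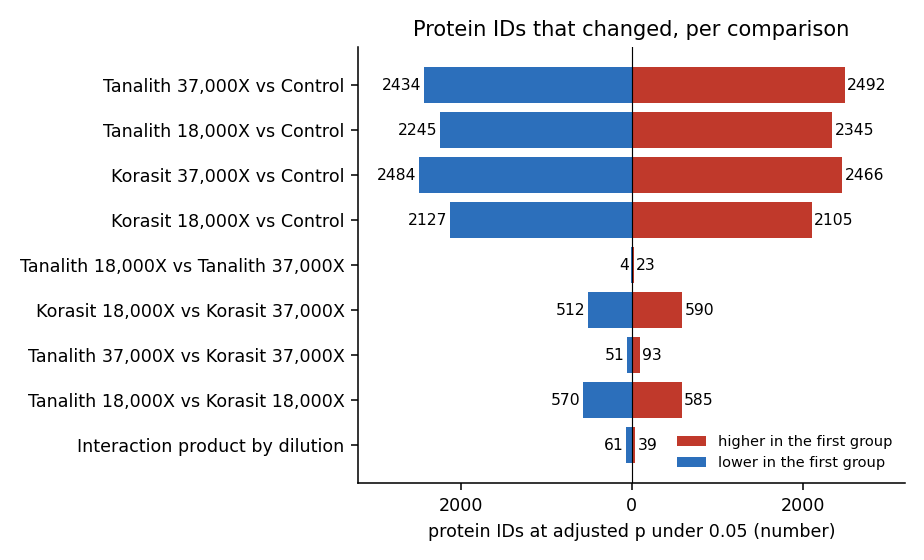
Number of protein IDs at an edgeR adjusted p below 0.05 in each comparison, with IDs higher in the first-named group to the right and lower to the left. In the interaction, IDs to the right had the higher log2 change from 37,000X to 18,000X under Tanalith. Treatment against control gave 4232 to 4950 IDs, the 2 Tanalith dilutions 27 and the 2 Korasit dilutions 1102.

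A large set of IDs moved in the same direction under every treatment. In all 4 treatments 1321 IDs rose and 1313 fell, out of 6907 that changed in at least 1, while 40 IDs rose in 1 treatment and fell in another. The 1321 IDs took 10.8% ± 0.564 of all counts in the control and 32.0% ± 0.760 in Tanalith 37,000X, 32.2% ± 1.08 in Tanalith 18,000X, 31.1% ± 0.927 in Korasit 37,000X and 29.5% ± 0.308 in Korasit 18,000X (SD, n = 3 each). The 1313 IDs took 18.8% ± 0.606 in the control and between 5.09% ± 0.0999 and 5.79% ± 0.474 in the treated groups. Both sets were defined by their change, so these shares give its size and are no separate test of it. The median log2 fold change was between 1.19 and 1.23 in the rising set and between -1.62 and -1.36 in the falling set. ID 6328981 rose in all 4 treatments, to 12521 ± 2321 CPM in Korasit 37,000X and 6252 ± 1960 CPM in Korasit 18,000X, and IDs 6472142 and 6417800 fell in all 4.

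The log2 fold changes of pairs of treatments correlated across IDs with Pearson's r between 0.784 and 0.899, where IDs are not independent replicates. The 4 comparisons use the same 3 control libraries. Sharing simulated controls gave a mean r of 0.498 to 0.506 between simulated unchanged groups. These simulations used 1 spread per ID for all groups, so noise particular to the real control libraries is not in them. The covariance was 1.08 to 1.34 for the pairs of treatments and 0.0877 to 0.0887 in the simulations. Pairs of treatments had 1530 to 2098 rising IDs in common, against 429 to 534 for independent lists of the same length and at most 0 in the simulations. They had 1533 to 1999 falling IDs in common, against 415 to 525 and again at most 0. The threshold ensures 0 shared IDs where nothing changes, so the simulations are no baseline for the number in common. A split of the 3 controls would leave 1 library on a side and was not made, so part of the excess over independent lists may come from the shared controls. With scaling by total count, 878 IDs rose and 1707 fell in all 4 treatments.

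**Figure D3:**
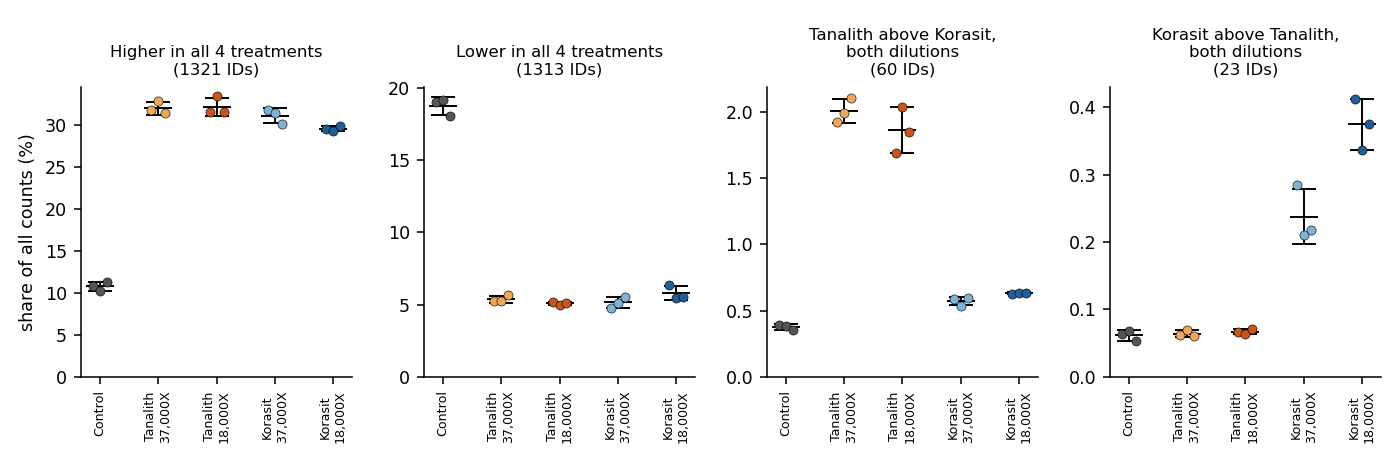
Share of all counts (%) taken by 4 sets of protein IDs in each library, with 1 point per library and the group mean ± SD of 3 libraries as bars. The sets were chosen by the tests of these libraries. IDs higher in all 4 treatments took 10.8% in the control and 29.5% to 32.2% in treated groups, and the 60 IDs higher under Tanalith than Korasit took 2.01% and 1.86% under Tanalith.

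Within Tanalith, the stronger dilution changed few IDs relative to the weaker one. At 18,000X 23 IDs were higher and 4 lower than at 37,000X. ID 6334096 was 6.20-fold higher, at 294 ± 31.0 against 47.4 ± 24.9 CPM (log2 fold change 2.63 ± 0.39 SE, adjusted p = 0.0103), where the control had 133 ± 44.2 CPM. ID 6122992 rose from 2.13 ± 1.05 to 11.4 ± 4.28 CPM (2.42 ± 0.43 SE, adjusted p = 0.0311). ID 6362692 fell from 70.5 ± 14.2 to 29.0 ± 5.06 CPM (-1.28 ± 0.24 SE, adjusted p = 0.0426) and ID 6326659 from 221 ± 66.9 to 91.6 ± 9.35 CPM (-1.27 ± 0.22 SE, adjusted p = 0.0315). DESeq2 called 119 IDs as higher and 117 as lower, a fit of these 6 libraries alone called 12 and ended the call of ID 6334096 (adjusted p = 0.0616), and scaling by total count gave 22 higher and 1 lower. The count was 8 without Tanalith 37,000X replicate 3, 73 without its replicate 2 (28 higher and 45 lower), and 15, 14 and 10 without Tanalith 18,000X replicates 1, 2 and 3, and IDs 6122992, 6362692 and 6326659 each lost the call in 4 of the 6 fits that left out a library.

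Within Korasit, 590 IDs were higher and 512 lower at 18,000X than at 37,000X, and the rises were the larger changes, with 437 IDs higher and 95 lower by 2-fold or more. The split was 447 higher and 517 lower with scaling by total count and 926 and 710 with DESeq2. ID 6386190 rose from 0.562 ± 0.518 to 23.7 ± 22.2 CPM (log2 fold change 5.36 ± 0.84 SE, adjusted p = 0.00292). Its Korasit 18,000X libraries were uneven, at 14.9, 7.19 and 48.9 CPM. ID 6471926, which had fallen to 1.14 ± 0.0766 CPM in Korasit 37,000X, stood at 46.1 ± 11.9 CPM in Korasit 18,000X (5.34 ± 1.31 SE, adjusted p = 0.0208). ID 5638821 fell from 155 ± 67.1 to 20.5 ± 15.03 CPM (-2.92 ± 0.71 SE, adjusted p = 0.0202) and ID 6295651 from 290.3 ± 127 to 43.7 ± 29.1 CPM (-2.73 ± 0.58 SE, adjusted p = 0.0115), against control levels of 3.23 ± 1.24 and 17.3 ± 8.61 CPM.

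A subset of the IDs changed by Tanalith moved in the opposite direction between the Korasit dilutions. Of the 683 IDs that changed both between the Korasit dilutions and in Tanalith 37,000X against the control, which have no library in common, 577 (84.5%) moved in opposite directions. For independent lists of the same length, 125 IDs higher at Korasit 18,000X and lower under Tanalith would be expected, and 283 were found. For the opposite combination 111 would be expected and 294 were found. Across all tested IDs Pearson's r was -0.293 and Spearman's rho -0.315, and with DESeq2 r was -0.171. Against Tanalith 18,000X, 503 of 633 IDs moved in opposite directions and r was -0.222. Between the Tanalith dilutions and Korasit against the control, r was -0.0728 at 37,000X and 0.0316 at 18,000X, and 3 of 20 and 0 of 19 IDs moved in opposite directions. An opposite change between the Korasit dilutions is not an opposite change against the control. Against the shared control libraries, 1583 IDs rose and 1534 fell under both Tanalith 37,000X and Korasit 18,000X, and 20 changed in opposite directions. At most 20 of the 577 IDs can therefore have changed in opposite directions against the control in these groups.

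The 2 Korasit groups also differed in depth and in transcript length. Korasit 37,000X libraries had 45354360 to 73943693 counts and Korasit 18,000X libraries 30373782 to 43152836. The log2 difference correlated with transcript length across IDs (rho -0.294), and the IDs higher at 18,000X had a median length of 1179.5 nt against 2259 nt for those lower. With the length trend removed, 841 IDs changed, of which 726 were among the 1102 and had the same direction, and 470 of 555 moved against Tanalith 37,000X. A fit of the 6 Korasit libraries alone called 1655 IDs. The count of 1102 was 612 without Korasit 18,000X replicate 1, 542 without its replicate 3, and 416, 329 and 705 without Korasit 37,000X replicates 1, 2 and 3, the last with 316 higher and 389 lower, and the calls of IDs 6471926 and 5638821 were lost in 3 and 4 of these 6 fits.

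**Figure D4:**
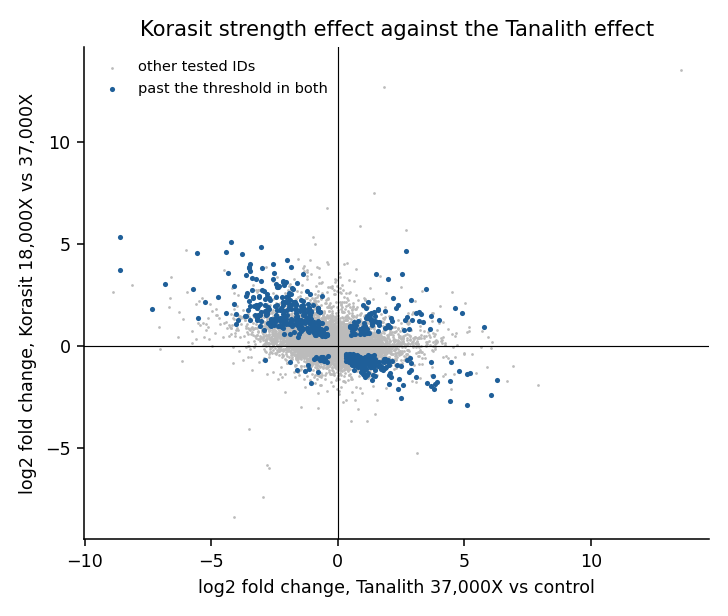
Log2 fold change between the Korasit dilutions (vertical axis) against that of Tanalith 37,000X and the control (horizontal axis), 1 point per protein ID, for 11511 IDs. Among the 683 IDs past the threshold in both comparisons (blue), 577 lie in the upper left and lower right of the plot. The vertical axis does not show Korasit against the control.

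The products were compared at equal dilution according to the labels, where they differ in the presence of azoles or quaternary ammonium compounds and, at 37,000X, in copper by 3 against 2.75 mg/L. At 37,000X 93 IDs were higher and 51 lower under Tanalith than under Korasit. ID 6350794 stood at 514 ± 200 CPM under Tanalith and 16.3 ± 4.09 CPM under Korasit, a log2 difference of 4.98 ± 0.31 (SE, adjusted p = 1.29e-06), and the control had 16.9 ± 4.75 CPM. ID 4166463 stood at 200.5 ± 54.9 against 9.80 ± 0.604 CPM (4.35 ± 0.34 SE, adjusted p = 5.45e-06), with 5.62 ± 3.14 CPM in the control. ID 6320077 was higher under Korasit, at 125 ± 93.8 against 2.81 ± 1.18 CPM (-5.48 ± 0.54 SE, adjusted p = 2.82e-05), as was ID 5480971 at 261 ± 150.2 against 27.9 ± 8.10 CPM (-3.23 ± 0.55 SE, adjusted p = 0.00613).

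At 18,000X the products differed in more IDs, with 585 higher and 570 lower under Tanalith, but 196 higher and 393 lower by 2-fold or more and 17 and 103 by 4-fold or more. The same 2 IDs led the Tanalith side, ID 4166463 at 204 ± 8.34 against 16.1 ± 4.28 CPM (3.66 ± 0.33 SE, adjusted p = 4.13e-05) and ID 6350794 at 475 ± 57.9 against 49.4 ± 7.25 CPM (3.27 ± 0.29 SE, adjusted p = 4.13e-05). On the Korasit side, ID 6320077 stood at 440 ± 109 against 8.09 ± 3.13 CPM (-5.77 ± 0.54 SE, adjusted p = 4.13e-05), and ID 6268431 at 68.7 ± 78.5 against 1.325 ± 0.168 CPM (-5.70 ± 1.19 SE, adjusted p = 0.00938). The Korasit 18,000X libraries of ID 6268431 were uneven, at 159, 15.6 and 31.7 CPM.

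At both dilutions 60 IDs were higher under Tanalith, where independent lists would have 4.73 in common, and 23 were higher under Korasit, against 2.53. The 2 comparisons have no library in common, and 2 IDs were in each list pair of opposite direction. Both sets were chosen on these treated libraries, so their changes against the control and their shares describe them and are no separate test. Of the 60 IDs, 56 rose against the control in each Tanalith group and 1 fell in Tanalith 37,000X, while 30 rose and 7 fell in Korasit 37,000X, and 33 rose and 5 fell in Korasit 18,000X. Their share of counts was 0.376% ± 0.0199 in the control, 2.01% ± 0.0924 and 1.86% ± 0.174 in Tanalith 37,000X and 18,000X, and 0.573% ± 0.0306 and 0.633% ± 0.00413 in Korasit 37,000X and 18,000X (SD, n = 3 each). Of the 23 IDs, 20 and 21 rose and 1 and 0 fell in Korasit 37,000X and 18,000X, and 11 and 12 rose and 2 and 4 fell in Tanalith 37,000X and 18,000X. Their share of counts was 0.0616% ± 0.00802 in the control, 0.0639% ± 0.00548 and 0.0669% ± 0.004 under Tanalith, and 0.238% ± 0.0409 and 0.375% ± 0.038 under Korasit at 37,000X and 18,000X.

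DESeq2 called 318 IDs between the products at 37,000X, and 61 IDs as higher under Korasit at both dilutions. A fit of the 6 libraries alone called 2003 IDs at 18,000X. The count at 37,000X was 90 and 82 without Korasit 37,000X replicates 1 and 2. The count at 18,000X was 689 and 496 without Korasit 18,000X replicates 1 and 3, and 408, 502 and 584 without Tanalith 18,000X replicates 1, 2 and 3, and the 23 IDs were 11 without Korasit 37,000X replicate 1.

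**Figure D5:**
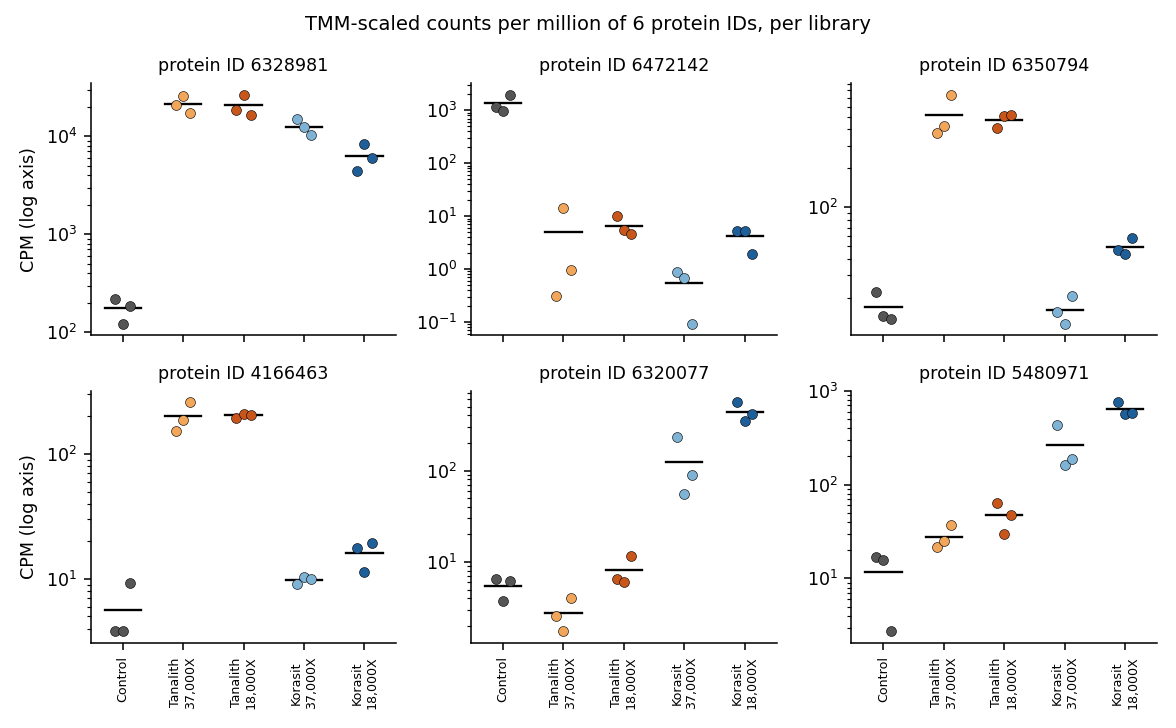
CPM with TMM scaling (log axis) of 6 protein IDs in each library, with a line at the mean of the 3 libraries of a group. ID 6328981 rose and ID 6472142 fell in all 4 treatments. IDs 6350794 and 4166463 were above 100 CPM under Tanalith and below 100 CPM under Korasit, and IDs 6320077 and 5480971 were higher under Korasit.

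The effect of dilution differed between the products in 100 IDs, of which 39 had the higher and 61 the lower log2 change under Tanalith. ID 6345160 rose from 1680 ± 109 to 5554 ± 1533 CPM from Tanalith 37,000X to 18,000X and fell from 5391 ± 1158 to 2212 ± 145 CPM between the Korasit dilutions, an interaction of 3.01 ± 0.39 (log2, SE, adjusted p = 0.00708). ID 6245847 stood at 32.0 ± 10.2 and 149 ± 9.17 CPM under Tanalith and at 138 ± 43.8 and 74.99 ± 17.2 CPM under Korasit at 37,000X and 18,000X, an interaction of 3.10 ± 0.47 (SE, adjusted p = 0.0132). ID 6172658 gave -3.91 ± 0.71 (SE, adjusted p = 0.0232) and ID 4441061 -4.59 ± 1.00 (SE, adjusted p = 0.0482).

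DESeq2 called 657 IDs in the interaction and gave no adjusted p for ID 4441061, a fit of the 12 treated libraries called 242, and scaling by total count gave 43 higher and 40 lower. The count was 354 without Tanalith 37,000X replicate 1 and 60 without its replicate 3, 13, 13 and 15 without Tanalith 18,000X replicates 1, 2 and 3, 55 and 15 without Korasit 18,000X replicates 1 and 3, and 14 and 11 without Korasit 37,000X replicates 2 and 3. The calls of IDs 4441061 and 6172658 were lost in 10 and 6 of the 12 fits that left out a library.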

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

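Thinning to equal depth and removal of the length trend were chosen after seeing the data, and the fit of the Tanalith dilutions without replicate 3 of the weaker group, planned as 1 of those that leave out a library, was chosen as a test of a deviating library after the result was seen. The effect of dilution differed between Tanalith and Korasit in 100 protein IDs by a test of the difference itself. When the 12 treated libraries were assigned at random to 4 groups of 3, 2 of 100 assignments gave at least as many IDs, the real one included, and the highest other gave 121. Such assignments also mix the products and the dilutions, which differed in up to 1155 and 1102 IDs, so they do not show whether chance can be excluded for the interaction. Its count was 11 without Korasit 37,000X replicate 3 and 354 without Tanalith 37,000X replicate 1. If the dilution labels of the Korasit groups were exchanged, which no value here decides, the Korasit part of the interaction would change sign and the products would not have been compared at equal dilution. The 4 IDs named for the interaction, for which overlap between libraries of 2 groups was not examined in choosing them, differed in their dilution effect (Tanalith minus Korasit, log2) by 3.10 for ID 6245847, 3.01 for ID 6345160, -4.59 for ID 4441061 and -3.91 for ID 6172658. The last 2 rest on uneven libraries, and libraries of the 2 dilutions overlap, those of Korasit in ID 4441061 and those of Tanalith in ID 6172658. ID 4441061 had 263 CPM in Korasit 18,000X replicate 1 and 26.9 and 36.1 CPM in the other replicates, and ID 6172658 had 313 CPM in Tanalith 37,000X replicate 2 and 64.9 and 73.5 CPM in the other replicates.

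The stronger dilution changed 27 IDs within Tanalith and 1102 within Korasit, and the interaction above is the only test of that contrast. Its size depends on the method, since DESeq2 gave 236 and 1636 IDs, and 1532 and 2893 had an unadjusted p below 0.05. With all libraries thinned to equal depth the Korasit count was still 38.9 times the Tanalith count, and with the trend over transcript length removed it was 35.0 times. Tanalith 37,000X replicate 3 lies far from its group and could have hidden changes, but without it the Tanalith dilutions differed in 8 IDs, against 73 without its replicate 2, and the Korasit dilutions in 329 without Korasit 37,000X replicate 2. A difference between the products in how much the stronger dilution adds is a hypothesis that stays open, beside differences between cultures that no label records.

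Each comparison of 2 groups has 10 splits of its 6 libraries, too few for a share below 0.05. The real split, 1 of the 10, gave the most IDs in all 8 comparisons. Where the 2 groups differ, every other split mixes them, which widens the spread within groups and lowers the count. The size of the gap between splits is therefore no measure of what chance gives. For Tanalith 37,000X against the control it gave 4926 IDs and the highest other split 1, for Tanalith 18,000X 4590 and 0, for Korasit 37,000X 4950 and 0, and for Korasit 18,000X 4232 and 0. Between the Tanalith dilutions it gave 27 and the highest other split 0, and between the Korasit dilutions 1102 and 0. Between the products it gave 144 and 0 at 37,000X and 1155 and 2 at 18,000X.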

How the results depend on the processing

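The values under scaling by total count, and all alternatives for the IDs shared by treatments or products and for the correlation of effects, were chosen after seeing the data. Of 36 tests of single IDs, 0 reversed their direction, 28 kept their call in all alternatives and 8 lost it in 44 fits in all. Leaving out 1 library moved the log2 fold change by more than 1 in 8 tests, those of IDs 6333962 (to -11.15), 6471926 (-6.26 and -9.80), 6104869 (11.7), 6410002 (-9.08), 6386190 (4.26), 6268431 (-4.16), 4441061 (-2.81) and 6172658 (-2.83). The gene lists were not run, with any setting, since no ID could be matched to a list. The fit of only the groups compared was not run for results that need more than 1 comparison. Median-of-ratios scaling, no filter on low counts, scaling by the deposited constants, removal of the length trend and thinning to equal depth kept the counts within 1.5 times. The cause of the changes below was not tested, except that a fold criterion keeps fewer IDs and leaving out a library leaves fewer samples.

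DESeq2 called 236 IDs between the Tanalith dilutions, 318 between products at 37,000X, 657 in the interaction and 61 higher under Korasit at both dilutions. Its fold changes gave r = -0.171 for the Korasit dilution effect against Tanalith 37,000X. They gave r = 0.837 for Tanalith 37,000X and Korasit 37,000X, 0.809 for Tanalith 18,000X and Korasit 37,000X, and 0.738 for the Korasit dilutions. A fit of only the groups compared called 3237 IDs for Tanalith 37,000X against the control, 12 and 1655 between the Tanalith and the Korasit dilutions, 2003 between products at 18,000X and 242 in the interaction. With a log2 change of at least 1 the counts against the control were 2758 and 2598 for Tanalith and 2750 and 2382 for Korasit at 37,000X and 18,000X, 532 between the Korasit dilutions, 589 between products at 18,000X, 589 higher and 798 lower in all 4 treatments and 39 higher under Tanalith at both dilutions. Scaling by total count left 878 IDs higher and 1707 lower in all 4 treatments, moved the median log2 fold change against the control by -0.27 to -0.12, and split Tanalith 18,000X into 1750 higher and 2486 lower.

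The side with more IDs turned under at least 1 alternative in each comparison except that of the products at 37,000X. Between the Korasit dilutions, 590 higher and 512 lower became 447 and 517 with scaling by total count and 316 and 389 without Korasit 37,000X replicate 3. Between products at 18,000X, 585 and 570 became 521 and 585 with median-of-ratios scaling and 773 and 899 with DESeq2. The Tanalith dilutions turned from 23 and 4 to 28 and 45 without Tanalith 37,000X replicate 2, and the interaction from 39 and 61 to 43 and 40 with scaling by total count.

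Leaving out 1 library gave 4068 to 5040 IDs for Tanalith 37,000X, 3725 to 4615 for Tanalith 18,000X, 3851 to 4919 for Korasit 37,000X and 3297 to 4290 for Korasit 18,000X against the control. It gave 8 (without Tanalith 37,000X replicate 3) to 73 (without its replicate 2) between the Tanalith dilutions and 329 (without Korasit 37,000X replicate 2) to 796 between the Korasit dilutions. Between products it gave 82 to 152 at 37,000X and 408 (without Tanalith 18,000X replicate 1) to 890 at 18,000X, and 11 (without Korasit 37,000X replicate 3) to 354 (without Tanalith 37,000X replicate 1) in the interaction. IDs higher in all 4 treatments were 1042 to 1455, lower 1022 to 1421, higher under Tanalith at both dilutions 45 to 58, under Korasit 11 (without Korasit 37,000X replicate 1) to 27, and r for the Korasit dilution effect -0.328 to -0.202.

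The 30 pairs of libraries with the same replicate number correlated at -0.206 to 0.284, 7 above 0.1. Of 15 libraries, 7 correlated best with their own number. With the replicate number as a block the counts were 4942, 4643, 4951 and 4266 against the control, 29 and 1056 between dilutions of Tanalith and Korasit, 159 and 1167 between products and 137 in the interaction. Of simulated 1.5-fold changes between Tanalith 37,000X and the control 1.49% were recovered, but with few changed IDs in the simulation the adjusted threshold is stricter than in the real data, so this is no limit for comparisons with many changed IDs.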

Other observations

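The list of the 100 most abundant transcripts differed between the control and each treatment. An ID can leave such a list without a fall past the threshold, and the overlap of the lists between replicates was not examined. Of the 100 most abundant protein IDs of the control, 41 were also among the 100 most abundant in Tanalith 37,000X, 38 in Tanalith 18,000X, 42 in Korasit 37,000X and 43 in Korasit 18,000X. The 4 treated lists had 64 IDs in common, of which 32 were on the control list. Among the control's 100, 38, 46, 44 and 33 fell by edgeR's test in Tanalith 37,000X, Tanalith 18,000X, Korasit 37,000X and Korasit 18,000X, and 12, 8, 7 and 10 rose. Among all tested IDs, 6 had a mean of at least 100 CPM in the control and less than 10 CPM in each of the 4 treated groups, and all 6 fell in all 4 by the test. In the other direction, 4 IDs had less than 10 CPM in the control and at least 100 CPM in each treated group, and all 4 rose in all 4. These IDs were chosen on the means of the libraries tested, so their calls are no separate test.

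Relative levels followed transcript length in some libraries. Spearman's rho between an ID's length and its log2 deviation from the mean of all 15 libraries was -0.216, -0.226 and -0.138 in the Korasit 18,000X replicates and 0.218, 0.177 and 0.0138 in the Korasit 37,000X replicates. The means differed by -0.330 (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 libraries allow). Under Tanalith the mean was -0.119 ± 0.148 at 18,000X and 0.0752 ± 0.230 at 37,000X (SD, n = 3 each), a difference within the spread of replicates (exact two-sided permutation test, p = 0.3). The 3 control libraries lay between -0.0497 and 0.0513.

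In this and the next paragraph the correlation, the IDs in all 4 treatments, thinning, removal of the length trend, scalings other than median-of-ratios, and the test of exchanged dilution labels were chosen after the result was seen. Of the 4926 IDs changed by Tanalith 37,000X, 577 changed in the opposite direction from the weaker to the stronger Korasit dilution (r = -0.293 across all tested IDs, and -0.171 with DESeq2). Of the 1321 IDs higher in all 4 treatments 64 rose and 72 fell between the Korasit dilutions, with a median of -0.0210 (log2). Of the 1313 lower ones 97 rose and 13 fell, with a median of 0.218. Both sets had to differ from the control at the stronger Korasit dilution, which leaves out IDs that returned to the control level there. Their medians therefore decide nothing about the opposite changes. Transcript length as the whole cause is argued against by r = -0.288 with the length trend removed. Thinning to equal depth gave r = -0.302. Thinning leaves the expected fold changes as they are, so it decides nothing about a bias tied to library depth. A single Korasit library as the whole cause is argued against by negative correlations in 9 of 9 pairs of 1 library from each dilution. They ranged from -0.385 to -0.0822. The 9 pairs reuse the same libraries and the same Tanalith effect, so they are not independent. An exchange of the dilution labels between the Korasit groups stays open: the 51 IDs higher under Korasit at 37,000X, with a median of -0.175 between the dilutions, were chosen on those libraries and decide nothing, as were the 23 IDs higher under Korasit at both dilutions, of which 7 rose and 1 fell. The cause of the opposite changes was not tested.

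The change of 1321 and 1313 IDs in the same direction in all 4 treatments was weighed against 3 technical explanations. Simulated groups without any effect, measured against shared simulated controls, gave at most 0 such IDs in 20 simulations. The threshold ensures this where nothing changes, so it is no test of the shared controls. The covariance of log2 fold changes between treatments was 1.08 to 1.34, against 0.0877 to 0.0887 in the simulations. This does argue against noise of the simulated size in shared controls, with 1 spread per ID for all groups, as the whole cause of that covariance. The simulations hold no spread particular to the real controls and no deviation common to all control libraries, so they decide nothing about either. Under 3 other scalings the lowest number was 2585, and with the length trend removed it was 2747. A shared response to what the products have in common, copper among it, is a candidate explanation that the design cannot separate from a general response to any inhibitor, since no group received copper alone, an azole alone or QAC alone.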
